A study of Rattus norvegicus with 7 samples.

How the data were processed

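Neonatal rat ventricular myocytes were infected with an Adssl1 adenovirus or a control adenovirus, and total RNA was sequenced on the BGISEQ-500 platform, per the labels. The values are raw counts of reads per gene in 1 table of 33294 gene symbols and 7 libraries, as deposited by the authors. The submitters' processing notes name HISAT2, STAR, featureCounts, Subread and DESeq2 and the genome build mRatBN7.2, with no versions and no order of use. The annotation and the use of strand are not given in the sources used here, so reads shared by overlapping or near-identical genes, such as ribosomal protein copies, cannot be placed with certainty. Gene symbols of an NCBI table for the assembly GRCr8 served to match older names only, and no coordinates were taken from it.

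Groups were taken from the sample titles. Library totals ran from 18677995 to 19143502 counts, and all pairs of replicates within a group differed beyond counting noise (chi-square per degree of freedom 3.13 to 50.5), so each library was counted once. Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15), which left 15235 genes. Counts were scaled with TMM factors and tested with edgeR's quasi-likelihood F test with robust fitting, Adssl1 against control with no covariate, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Levels are CPM with TMM-scaled library sizes. The standard error of a log2 fold change was derived from the F statistic. Exact counting intervals at 95% and the floor of 3 counts over a group cover counting error only.

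The 29 gene lists and the rule for named genes were fixed before the data were examined. Named genes were Adss1, the 10 largest rises and 10 largest falls among called genes with mean log2 CPM of at least 1 and groups that did not overlap, leaving out identifiers without a symbol, and per list up to 2 members with the smallest adjusted p in the main direction and 1 in the other. A further 20 genes were chosen after their values were seen. Of 634 list entries 629 were matched to the table (607 as written, 14 by an alias, 8 by a synonym) and 596 entries were tested. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 (camera adjusted p), with camera at an estimated correlation, and with fry. With fry's directional test, which does not compare a list with other genes, 18 lists passed.

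The tests were tried on 10 simulated sets with 200 changed genes among 15235, drawn from the means, library sizes and gene-wise dispersions of this comparison. edgeR recovered 51.8%, 79.7% and 93.5% of genes changed 1.5-fold, 2-fold and 4-fold. The mean share of false calls was 8.90% for edgeR (3.85% to 15.8% over the sets), 8.71% for limma voom and 15.0% for DESeq2, above the nominal 5% in each case. With dispersions set to their smooth trend the shares were 4.75%, 4.38% and 6.36%. In the data 48.2% of tested genes were called, far more than the 200 of 15235 changed in the simulation. The recovered and false shares therefore cannot be carried over to the real calls. A first version with a single set had been set to stop at a false share of 15%, which DESeq2 exceeded there; the limit was then kept for edgeR's mean alone, since DESeq2 served as an alternative only. Lists of unchanged genes reached p under 0.05 in 0.3% of cases with camera's preset correlation, 0.1% with its estimated correlation and 6.6% with fry, in simulated genes that vary independently, unlike real ones.

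Alternatives were other scalings (RLE, upper-quartile, total counts), DESeq2 1.42.0, limma voom with sample weights, other low-count filters (none, or CPM of at least 1 in 3 libraries), thinning to the smallest library, Adssl1 left out, the replicate number as a block, each library left out in turn, stricter thresholds (adjusted p under 0.01, or a 2-fold change) and the other set tests. Leaving out Adssl1 replicate 4 and control replicate 3 together was added after the data were seen. The labels name no batch.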

Results

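RNA sequencing was performed on neonatal rat ventricular myocytes, primary heart muscle cells taken from newborn rats, that had been infected with an adenovirus carrying Adssl1 or with a control adenovirus. Adssl1, now named Adss1, encodes the muscle form of adenylosuccinate synthase, which acts in the purine nucleotide cycle. The control group had 3 libraries and the Adssl1 group had 4, all at a multiplicity of infection of 20 and with RNA taken 48 h after the medium was changed. The control libraries held 19096168, 19087201 and 19143502 gene-assigned reads in replicates 1 to 3. The Adssl1 libraries held 18791996, 18854890, 18677995 and 19047910 in replicates 1 to 4. Of 33294 genes in the count table, 9042 had no count in any library and 15235 were tested. The labels do not say whether replicates came from separate cell isolations, so p-values measure the spread between these libraries, which may be technical.

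The overexpressed gene was examined first, because its level checks the group labels. Adssl1 rose from 40.8 ± 8.70 CPM (counts scaled to library size, SD, n = 3) in the control libraries to 93437 ± 38376 CPM (SD, n = 4) in the Adssl1 libraries. The log2 fold change was 11.16 (SE 0.46, edgeR adjusted p = 9.15e-07), and every library lay on the side its label gives. Adssl1 took 7.84%, 7.47%, 7.68% and 14.2% of all counts in Adssl1 replicates 1 to 4, so replicate 4 stood apart from the other 3. In the control libraries its share lay between 0.00323% and 0.00496%. The counts do not tell transcripts of the virus from those of the cells' own gene.

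**Figure D1:**
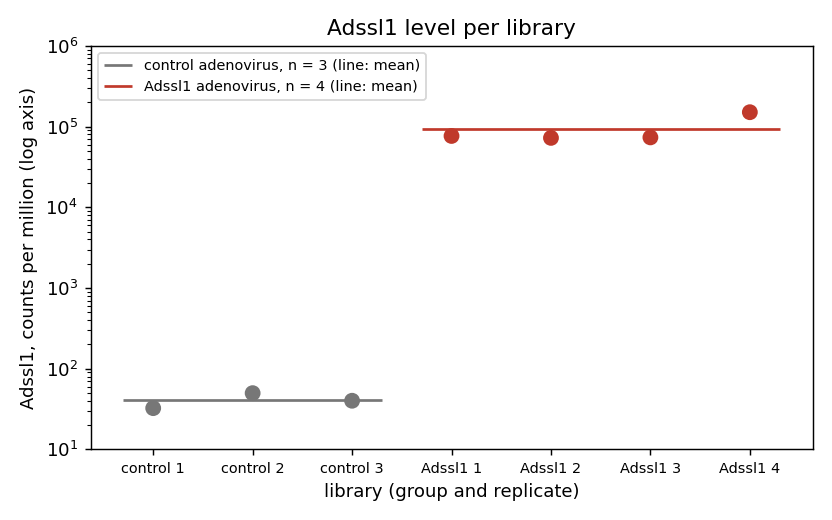
Adssl1 level in each library, in CPM on a log axis. Points are libraries and horizontal lines are group means. The 3 control libraries lie between 32.5 and 49.8 CPM, and the 4 Adssl1 libraries between 72553 and 150942 CPM.

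The study's stated purpose was to learn how Adssl1 acts on cardiomyocyte proliferation, and the comparison of both groups answers which transcripts differ after its overexpression. Between the groups 7349 of 15235 genes changed, 3639 of them higher and 3710 lower with Adssl1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 1071 were at least 2-fold higher and 883 at least 2-fold lower. The CPM ranges of the groups did not overlap for 7947 tested genes, 52.2% of them, where chance gives 5.71%. The first principal component held 76.2% of the variance and parted the groups.

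Among the largest rises was Il6, an inflammatory cytokine, which rose from 0.442 ± 0.0851 to 41.5 ± 22.6 CPM (SD, n = 3 and n = 4, log2 fold change 6.53, SE 0.62, edgeR adjusted p = 0.000162). Adra2a, an adrenergic receptor, rose by 6.26 on the log2 scale (SE 0.19, edgeR adjusted p = 2.75e-08), and the neuropeptide Y receptor Npy1r rose by 6.10 (SE 0.34). Ano5 (5.79, SE 0.23), Ism1 (6.72, SE 0.43) and the peptide hormone gene Cck (5.55, SE 0.74) rose as well. Cyp26a1, which degrades retinoic acid, had 265 counts with Adssl1 and 1 in the controls, a 198-fold difference (95% exact counting interval 35.2 to 7834). The transcription factor gene Tfap2c had 397 counts against 2, a 148-fold difference (interval 40.7 to 1227). The difference was at least 43.8-fold for Cyp26a1 without control replicate 2, and without control replicate 1 it was 131-fold for Cyp26a1 and 98.5-fold for Tfap2c. Bpifb1 had 483 counts with Adssl1 and none in the controls, at least 120.1-fold higher against a floor of 3 counts over the group. Adssl1 replicate 3 held 323 of the 483 counts, and without it the difference was at least 53.5-fold, and at least 79.8-fold without control replicate 2 or 79.9-fold without control replicate 1. Its call was lost without control replicate 2 (edgeR adjusted p = 0.0601) or control replicate 3 (edgeR adjusted p = 0.0551), and with no low-count filter (edgeR adjusted p = 0.105).

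Several of the largest falls were in genes of the immune system. C7, a complement component, fell from 533.9 ± 26.3 to 11.9 ± 2.84 CPM (SD, n = 3 and n = 4, log2 fold change -5.49, SE 0.16, edgeR adjusted p = 2.93e-08). The macrophage genes Adgre1 (-7.01, SE 0.38) and Lyz2 (-5.37, SE 0.30) fell, as did Cd4 (-5.31, SE 0.28), Lilrb4 (-4.86, SE 0.28) and Cybb (-4.67, SE 0.41), a subunit of the phagocyte NADPH oxidase. Fcrl2 had 2 counts with Adssl1 and 367 in the controls, a 246-fold difference (95% exact counting interval 67.6 to 2040), or at least 125-fold without Adssl1 replicate 4, which held both counts. Akr1c14 (-5.00, SE 0.25), Them5 (-4.82, SE 0.47) and the matrix gene Spon1 (-4.41, SE 0.26) completed the 10 largest falls.

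**Figure D2:**
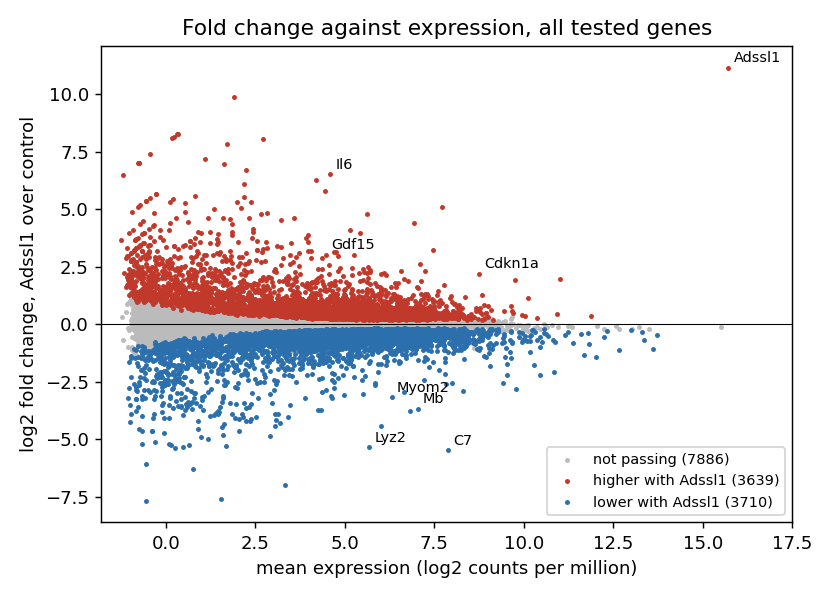
Log2 fold change (Adssl1 over control) against mean expression in log2 CPM for the 15235 tested genes. Red and blue points passed the test. Adssl1 has a log2 fold change of 11.16, and 3639 higher and 3710 lower genes lie on both sides of 0.

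Gene groups were described with 29 lists fixed before the data were examined, of which 28 had enough tested members. The camera test with a preset correlation called 6 lists higher and 7 lower, and with an estimated correlation it called 0, the smallest adjusted p being 0.103 with an estimated correlation. Of the 35 ways to split these 7 libraries into 4 and 3, 20, the real one included, gave at least 13 called lists, so the number of called lists did not set the real grouping apart. The counts of single members below rest on the test of each gene. Of all 15235 tested genes 48.2% changed, 3639 of them higher and 3710 lower. Member counts near that share do not set a list apart from other genes.

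Genes of DNA replication and S phase rose: 21 of 30 members were higher and none lower, over all genes and when adjusted over the list alone (median log2 fold change 0.50, camera adjusted p = 2.92e-08, adjusted p = 0.449 with an estimated correlation). Tyms, which makes thymidylate, rose by 1.11 (SE 0.07) and the flap endonuclease gene Fen1 by 1.11 (SE 0.08). Ccne1 (1.84, SE 0.14) and Ccne2 (1.99, SE 0.16), cyclins of the step into S phase, were singled out after their values were seen. In the mitosis and cytokinesis list 7 of 30 members were higher and none lower, 5 when adjusted over the list alone, and the list was not called (median 0.18, camera adjusted p = 0.227). Tpx2 (0.57, SE 0.12) and Incenp (0.42, SE 0.08) rose, while Mki67, chosen after its value was seen, was at 67.0 ± 12.7 and 68.3 ± 11.5 CPM (SD, n = 3 and n = 4, edgeR adjusted p = 0.893). The number of higher mitosis genes was 4 without control replicate 1 and also without control replicate 2, and 11 without Adssl1 replicate 3. The mitosis list was called without control replicate 3 (camera adjusted p = 0.0465) and without Adssl1 replicate 3 (camera adjusted p = 0.0332), and with all libraries under limma voom (camera adjusted p = 0.00662, 15 higher).

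Inhibitors of cyclin-dependent kinases and targets of p53 rose in the same libraries. Of 24 members 16 were higher and 3 lower, 16 and 4 when adjusted over the list alone (median 0.61, camera adjusted p = 1.06e-07, adjusted p = 0.103 with an estimated correlation). Cdkn1a, which encodes p21, rose from 139.9 ± 9.42 to 643.9 ± 61.4 CPM (SD, n = 3 and n = 4, log2 fold change 2.20, SE 0.10, edgeR adjusted p = 1.15e-07). Cdkn1c rose by 2.90 (SE 0.14), Mdm2, chosen after its value was seen, rose by 1.61 (SE 0.08), and Cdkn2d moved the other way (-0.99, SE 0.10). Among cyclin D, growth regulator and Myc family genes 6 of 22 were higher and 3 lower, likewise when adjusted over the list alone, and the list was not called (median 0.06, camera adjusted p = 0.549). Hand2 (0.95, SE 0.11) and Wwtr1 (0.43, SE 0.08) rose and Cdk6 fell (-0.70, SE 0.10). Mycn, chosen after its value was seen, had a log2 fold change of -0.06 (SE 0.14, edgeR adjusted p = 0.733). Beside these cell cycle groups, the leukocyte and fibroblast lists had medians of -4.13 and -1.15. The counts come from whole cultures, so they do not tell which cell type held the cell cycle changes.

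Sarcomere and adult contractile genes fell: 20 of 24 members were lower and 1 higher, likewise when adjusted over the list alone (median -0.84, camera adjusted p = 3.04e-11, adjusted p = 0.449 with an estimated correlation). Myom2, an M-band protein gene, fell from 160.5 ± 21.8 to 17.6 ± 1.52 CPM (SD, n = 3 and n = 4, log2 fold change -3.19, SE 0.11, edgeR adjusted p = 2.93e-08), and the ventricular light chain gene Myl2 fell by 2.10 on the log2 scale (SE 0.12). Myh6 (-1.78, SE 0.21) and Actc1 (-0.70, SE 0.18) fell as well, and Tnnt2 did not pass (-0.13, SE 0.09, edgeR adjusted p = 0.253); these and the oxygen-binding protein gene Mb (-3.68, SE 0.14), which is in no list, were chosen after their values were seen. Xirp1 was the member that was higher (0.27, SE 0.09), a call lost without control replicate 2 (edgeR adjusted p = 0.0737), control replicate 3 (edgeR adjusted p = 0.100) or Adssl1 replicate 2 (edgeR adjusted p = 0.0671). Fetal and stress-induced cardiac genes went both ways, with 7 of 19 lower and 3 higher, likewise when adjusted over the list alone, and were not called (median -0.35, camera adjusted p = 0.215). Tnni1 (-1.20, SE 0.07) and Myl7 (-0.84, SE 0.09) fell, and Gdf15, a stress-induced cytokine, rose by 3.02 (SE 0.16). Myh7 (-1.01, SE 0.13) and Nppa (-0.35, SE 0.08), chosen after their values were seen, fell too. Of calcium handling and ion channel genes 11 of 24 were lower and 2 higher, likewise when adjusted over the list alone (median -0.36, camera adjusted p = 0.113), with a fall of Hrc (-1.19, SE 0.13) and a rise of Kcnd2 (3.49, SE 0.37). That list was called without control replicate 2 (camera adjusted p = 0.0135), and its higher members were 5 without control replicate 3. In the same comparison markers of fibroblasts (median -1.15) and of leukocytes (median -4.13) fell too.

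Nuclear genes of oxidative phosphorylation fell nearly as a block: 29 of 30 members were lower and none higher, and 30 were lower when adjusted over the list alone (median -0.69, camera adjusted p = 2.17e-13, adjusted p = 0.449 with an estimated correlation). Uqcrc2 (-0.90, SE 0.07) and Ndufv2 (-0.92, SE 0.08), subunits of respiratory complexes, fell. Transcripts of the mitochondrial genome had 4 of 13 members lower and none higher, likewise when adjusted over the list alone, and were not called (median -0.23, camera adjusted p = 0.0984). COX3 fell by 0.47 on the log2 scale (SE 0.09) and ND3 by 0.39 (SE 0.09). Without Adssl1 replicate 4 this list was called (camera adjusted p = 0.0259) with 12 members lower, as it was in 4 alternatives including limma voom (camera adjusted p = 0.00362, 11 lower), and 2 were lower without control replicate 1 or 3 or Adssl1 replicate 1 or 2. Of all counts, mitochondrial transcripts took 12.7% ± 0.185 in the control libraries (SD, n = 3) and 11.1% ± 0.424 in the Adssl1 libraries (SD, n = 4), or 12.3% ± 0.810 of counts other than Adssl1. Fatty acid oxidation and uptake genes fell, 15 of 25 lower and none higher, 15 and 2 when adjusted over the list alone (median -0.49, camera adjusted p = 0.000842, adjusted p = 0.667 with an estimated correlation). Acadm (-0.85, SE 0.08) and Decr1 (-0.81, SE 0.09) were among the lower ones. Higher fatty acid members numbered 2 without control replicate 3 and 1 without Adssl1 replicate 2 or 4. Cholesterol and fatty acid synthesis genes fell, 20 of 27 lower and none higher, 21 and none when adjusted over the list alone (median -0.62, camera adjusted p = 4.57e-05, adjusted p = 0.731 with an estimated correlation), among them Srebf1 (-1.10, SE 0.14). Mvk fell from 25.7 ± 5.51 to 12.9 ± 0.431 CPM (SD, n = 3 and n = 4, edgeR adjusted p = 0.000185). Glycolysis genes were not called (8 of 23 lower, 1 higher; 5 and 1 when adjusted over the list alone, median -0.50, camera adjusted p = 0.124), with Ldhb (-0.54, SE 0.10) and Pfkm (-0.61, SE 0.13) lower and Eno3 (0.80, SE 0.20) higher, a call lost without Adssl1 replicate 4 and control replicate 3 together (edgeR adjusted p = 0.0530). Without control replicate 2, 13 glycolysis genes were lower and the list was called (camera adjusted p = 0.00336), while 4 or 5 were lower without control replicate 1 or 3 or Adssl1 replicate 1, 2 or 3, and 3 were higher without control replicate 3. Leukocyte and fibroblast markers, at medians of -4.13 and -1.15, moved with these groups.

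Genes around the overexpressed enzyme were examined next. In the purine nucleotide cycle and purine synthesis list 10 of 19 members, Adssl1 itself among them, were higher and 2 lower, likewise when adjusted over the list alone (median 0.22, camera adjusted p = 0.0102, adjusted p = 0.449 with an estimated correlation). The call rested on Adssl1: with it left out, the list was not called (camera adjusted p = 0.123). Without control replicate 1, or with a replicate block, 6 members were higher and 1 lower. The lower members also numbered 1 without control replicate 2 or Adssl1 replicate 4. Ppat, the first enzyme of de novo purine synthesis, rose by 0.79 (SE 0.07) and Impdh1 fell (-0.39, SE 0.07). Adss, the gene of the non-muscle synthase, rose by 0.31 (SE 0.08), and Adsl did not pass (-0.14, SE 0.12, edgeR adjusted p = 0.351); both were chosen after their values were seen. Adsl passed as lower without Adssl1 replicate 3 (edgeR adjusted p = 0.0387). In purine salvage and breakdown 2 of 15 were higher and 5 lower, likewise when adjusted over the list alone, and the list was not called (median -0.17, camera adjusted p = 0.328). Entpd1 (-1.76, SE 0.10) and Adk (-0.62, SE 0.09) fell and Dck (1.04, SE 0.11) rose. Entpd1 is also expressed by leukocytes, whose list had a median of -4.13.

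Markers of other cell types that a neonatal ventricular preparation can hold were tested in the same way. All 15 tested macrophage and leukocyte markers were lower, likewise when adjusted over the list alone (median -4.13, also with 1 gene at 0 set to its bound, camera adjusted p = 5.05e-27, adjusted p = 0.103 with an estimated correlation). Laptm5 fell from 18.3 ± 3.73 to 1.01 ± 0.206 CPM (SD, n = 3 and n = 4, log2 fold change -4.18, SE 0.20, edgeR adjusted p = 1.39e-07) and Fcer1g fell by 3.92 on the log2 scale (SE 0.19). Of fibroblast and matrix markers 15 of 21 were lower and none higher, likewise when adjusted over the list alone (median -1.15, camera adjusted p = 3.13e-16, adjusted p = 0.103 with an estimated correlation). Dpt (-3.72, SE 0.16) and Fbln1 (-1.76, SE 0.08) fell. Col1a1 (-1.08, SE 0.11) and Postn (-2.19, SE 0.12) fell too, while Fn1 (-0.10, SE 0.14, edgeR adjusted p = 0.584) and Thy1 (0.18, SE 0.14, edgeR adjusted p = 0.297) did not pass; these 4 were chosen after their values were seen. Fn1 passed as lower without Adssl1 replicate 4 (edgeR adjusted p = 0.0282), and Thy1 passed as higher without Adssl1 replicate 3 (edgeR adjusted p = 0.0336). With all libraries kept, Fn1 passed as lower under the replicate block (edgeR adjusted p = 0.0404) and limma voom (voom adjusted p = 0.0467). It also did without both farthest libraries (edgeR adjusted p = 0.0193). Thy1 passed as higher under voom (voom adjusted p = 0.0351). Epicardial and mesothelial markers were not called (6 of 11 higher, 2 lower; 6 and 3 when adjusted over the list alone, median 0.83, camera adjusted p = 0.215), with Krt18 (1.84, SE 0.20) and Krt8 (1.61, SE 0.22) higher and Wt1 lower (-1.48, SE 0.20). Endothelial markers (3 of 15 higher, 1 lower, median -0.16, camera adjusted p = 0.994), smooth muscle and pericyte markers (2 of 13 higher, 3 lower, median -0.02, camera adjusted p = 0.549) and Schwann and neuronal markers (2 of 6 higher, 2 lower, median -0.30, mean 0.18, camera adjusted p = 0.798) were not called, with the same counts when adjusted over each list alone. Sox17 rose (2.27, SE 0.24) and Plvap fell (-1.92, SE 0.28) among endothelial genes, and the pericyte genes Pdgfrb (-0.82, SE 0.09) and Notch3 (-1.43, SE 0.15) fell while Cspg4 (0.41, SE 0.10) rose. Egfl7 rose among endothelial genes (0.50, SE 0.15), a call lost without control replicate 1 (edgeR adjusted p = 0.0737) or 2 (edgeR adjusted p = 0.0660). Among Schwann and neuronal genes Foxd3 (2.03, SE 0.49) and Ngfr (0.98, SE 0.32) rose and Tubb3 (-0.61, SE 0.14) fell. The call of Ngfr was lost without control replicate 1 (edgeR adjusted p = 0.103) or 2 (edgeR adjusted p = 0.0572), or Adssl1 replicate 1 (edgeR adjusted p = 0.0546) or 2 (edgeR adjusted p = 0.0723). The small member counts of these lists moved when 1 library was left out, the endothelial ones to 1 higher (without control replicate 1 or 2), 2 lower (without control replicate 1 or 3) or 4 lower (without Adssl1 replicate 4). Higher smooth muscle members numbered 1 without control replicate 1 or 2 or Adssl1 replicate 1 or 2, and lower epicardial members 4 without control replicate 3. Lower Schwann members numbered 1 without control replicate 1. Higher Schwann members numbered 0 without Adssl1 replicate 1 or 2 and 1 without control replicate 1 or 2 or Adssl1 replicate 4. Only 1 of 11 erythroid markers could be tested, so that list has no result.

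**Figure D3:**
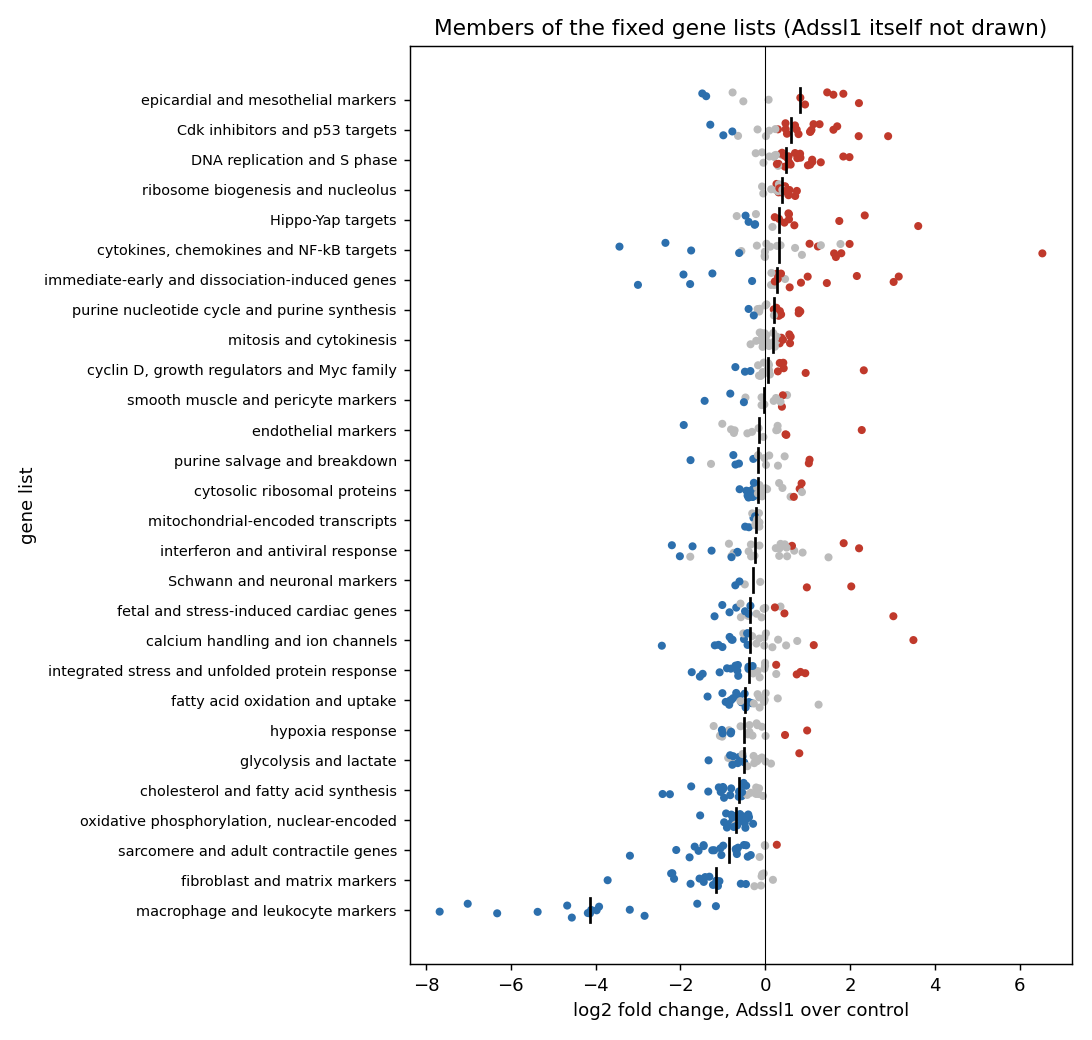
Log2 fold changes (Adssl1 over control) of the tested members of 28 gene lists, ordered by median; Adssl1 is not drawn, each point is a gene, red and blue points passed the test and black bars are medians. Leukocyte markers lie lowest at a median of -4.13, followed by fibroblast markers at -1.15 and sarcomere genes at -0.84.

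Growth, stress and infection genes gave a mixed account. Ribosome biogenesis genes rose, 14 of 24 higher and none lower, 15 and none when adjusted over the list alone (median 0.40, camera adjusted p = 0.00824, adjusted p = 0.784 with an estimated correlation). Nop58 (0.71, SE 0.10) and Gnl3 (0.55, SE 0.09) rose, and the higher members numbered 8 without control replicate 1 and 7 without control replicate 3. Cytosolic ribosomal protein genes were not called (3 of 29 higher, 13 lower; 4 and 16 when adjusted over the list alone, median -0.18, camera adjusted p = 0.195), with Rpl3 (-0.60, SE 0.07) lower and Rps19l2 (0.67, SE 0.16) higher. Of Hippo-Yap targets 10 of 17 were higher and 4 lower, 11 and 5 when adjusted over the list alone (median 0.32, camera adjusted p = 0.00532, adjusted p = 0.628 with an estimated correlation). Areg, a ligand of the EGF receptor, rose by 3.61 (SE 0.18), Nuak2 rose by 1.74 (SE 0.12), and Axl fell (-0.46, SE 0.09). The lower Hippo-Yap members numbered 1 or 2 without any single control library, and also without Adssl1 replicate 1 or 2. Of immediate-early and dissociation-induced genes 11 of 20 were higher and 5 lower, likewise when adjusted over the list alone (median 0.28, camera adjusted p = 0.0139, adjusted p = 0.628 with an estimated correlation), and 7 were higher without control replicate 1. The heat shock gene Hspa1b (3.15, SE 0.11) and Nr4a3 (3.03, SE 0.25) rose. Egr3 fell from 2.47 ± 0.513 to 0.302 ± 0.0431 CPM (SD, n = 3 and n = 4, edgeR adjusted p = 1.35e-05). Integrated stress and unfolded protein response genes fell on balance, 14 of 26 lower and 4 higher, 16 and 4 when adjusted over the list alone (median -0.39, camera adjusted p = 0.0102, adjusted p = 0.775 with an estimated correlation), with Atf5 (-1.48, SE 0.11) and Aldh1l2 (-1.73, SE 0.15) lower and Cebpb (0.83, SE 0.12) higher. Leukocyte markers (median -4.13) and fibroblast markers (median -1.15) fell in the same comparison.

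Interferon and antiviral genes were not called (3 of 29 higher and 7 lower; 0 and 0 when adjusted over the list alone, median -0.25, camera adjusted p = 0.676). Mx1 (-2.20, SE 0.51) and Xaf1 (-0.80, SE 0.21) fell and Cxcl10 rose (2.21, SE 0.61), the latter lost without control replicate 1 (edgeR adjusted p = 0.0558), 2 (edgeR adjusted p = 0.0555) or 3 (edgeR adjusted p = 0.0672). Without control replicate 3, 12 interferon genes were lower and the list was called (camera adjusted p = 0.0322), while 2 were lower without control replicate 1 or 2 and 4 without Adssl1 replicate 2 or 3. The higher members numbered 0 or 1 without any single control library or without Adssl1 replicate 1 or 2, and 5 without Adssl1 replicate 3. With a replicate block 9 interferon genes were higher and 13 lower, and with no low-count filter 0 and 2. Cytokine, chemokine and NF-kB genes were not called (7 of 24 higher, 4 lower, likewise when adjusted over the list alone, median 0.32, camera adjusted p = 0.328), with Il33 higher (1.67, SE 0.17) and Il1b, a product of macrophages, lower (-3.44, SE 0.41) beside the leukocyte median of -4.13. Hypoxia genes were not called (2 of 20 higher, 4 lower, likewise when adjusted over the list alone, median -0.50, camera adjusted p = 0.328). Adm rose (0.99, SE 0.14) and P4ha1 (-1.02, SE 0.20) and Ddit4 (-0.80, SE 0.20) fell. Without control replicate 2, 9 hypoxia genes were lower and the list was called (camera adjusted p = 0.0188), while 2 were lower without Adssl1 replicate 2 or 3. The higher members numbered 1 without control replicate 1 or 2 and 4 without control replicate 3.

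**Figure D4:**
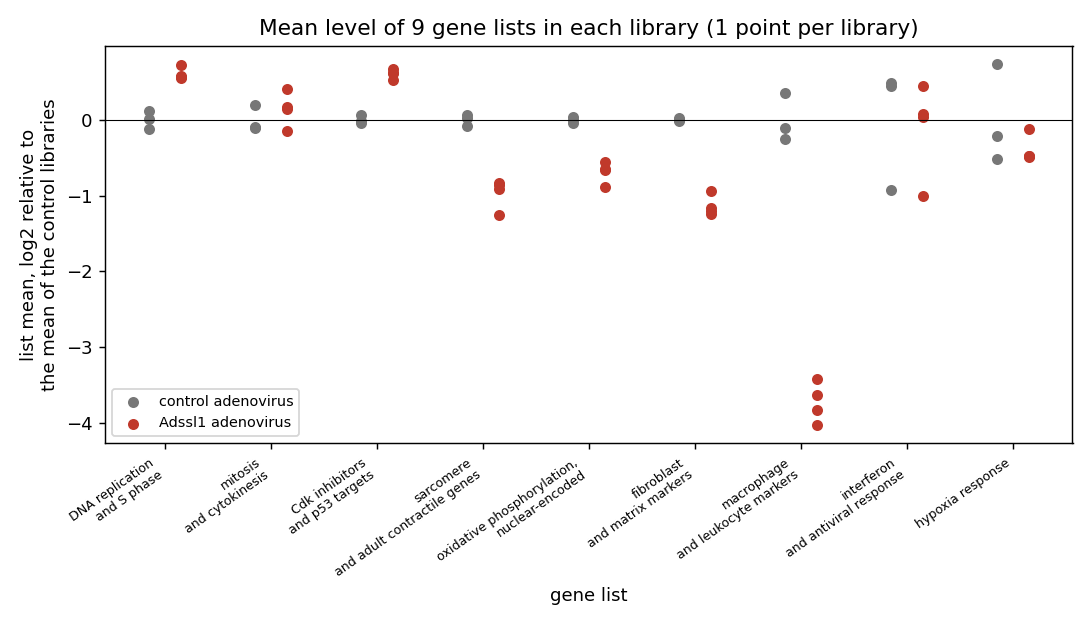
Mean log2 level of 9 gene lists in each library, relative to the mean of the control libraries; each point is 1 library. The groups part for the S phase, p53, sarcomere, oxidative phosphorylation, fibroblast and leukocyte lists, while they overlap for the mitosis, interferon and hypoxia lists. Control replicate 3 lies at -0.93 (interferon) and 0.73 (hypoxia). For the interferon list replicate 3 is the lowest library of the Adssl1 group too.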

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

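Of the tests in this part, only the counts over other splits of the libraries were planned; the others, and the genes of the added leukocyte list, were chosen after the results had been seen.

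Of 148 results compared within the 4 Adssl1 libraries, 14 had 1 library far from the other 3. For a single result chance gives about 1 in 20. Some of the results restate each other, such as the Adssl1 level and the Adssl1 share of counts. The 14 therefore cannot be weighed against that rate. Each value that follows is the gap to the nearest library as a share of the group's range. Replicate 4 was highest for the Adssl1 share of counts (0.944), the share of the 10 most abundant genes (0.868; 25.98% against at most 20.04%), the Adssl1 level (0.925), Il6 (0.864), Nr4a3 (0.950) and the hypoxia list (0.957), and lowest for Actc1 (0.888). Replicate 4 was also highest for Fcrl2 (1.00), where the other 3 libraries had no count. Replicate 3 was highest for Bpifb1 (0.926) and Cdk6 (0.964) and lowest for Gdf15 (0.921), Hrc (0.984), Pdgfrb (0.867) and Mx2 (0.832).

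For the 7349 changed genes, 1 of the 35 splits of the libraries into 4 and 3 gave as many, the real one, and the highest of the other splits gave 1 gene. At an unadjusted p under 0.05 the real split gave 8385 genes and the others up to 4527. The real split thus ranked first of 35 for the gene count, an exact permutation p of 0.0286. Splits that mix the groups spread the real difference within groups, so the 7349 against 1 overstates the distance. The rank sets the labelled grouping apart from the other splits. It cannot tell an effect of Adssl1 from other differences between the cultures. For Adss1 the log2 fold change of 11.16 was likewise reached by 1 of 35 splits, the highest other being 2.47. The virus carries this gene, so that rank only checks the labels. The number of called lists did not set the real split apart: 20 of 35 splits gave at least 13, and the highest of the other splits gave 18. The other splits mix the groups and carry part of the real difference. This count therefore cannot exclude chance and cannot show it. A test of each list's own mean level, chosen after that count was seen, ranked the real split first for 15 of 28 lists, among them all 13 called ones, each with a two-sided exact permutation p of 0.0286. That is the smallest p 35 splits can give, and after adjustment over the lists it is 0.0533, so no list passed. The mean of the purine list holds Adssl1 itself, so the rank of that list was set in part by the overexpressed gene.

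Leukocyte markers fell at a median of -4.13. Crowding out by Adssl1 reads is argued against by size: it can lower any other gene by at most 0.22 on the log2 scale (-0.22 in replicate 4), while the median in plain shares of all counts was -4.10. Fewer leukocytes in the Adssl1 cultures may account for the fall: of 26 tested leukocyte genes outside the fixed list 88.5% were lower, although that list was written after many falls had been seen. Whether Adssl1 lowered their number or those dishes held fewer from the start stays open, because the labels do not tie dishes to isolations.

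Sarcomere genes fell at a median of -0.84. Crowding out is argued against here too, since the median in plain shares was -0.81 against a largest possible loss of -0.22. A smaller share of cardiomyocytes alone would raise the markers of other cell types alike, and these moved apart: the fibroblast markers had a median of -1.15 with an upper quartile of -0.26, and the endothelial, smooth muscle and epicardial medians were -0.16, -0.02 and 0.83. That argues against it as the sole cause, as far as marker levels track cell numbers. A larger share of epicardial cells stays open. Of those markers 6 of 11 were higher and 2 lower, Wt1 among the lower (-1.48), and the list was not called (camera adjusted p = 0.215). A direct or indirect effect of Adssl1 on contractile genes stays open and was not tested further.

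S phase genes rose while the mitosis list was not called. The counts do not tell whether this took place in cardiomyocytes or in other cells of the cultures. More dividing cells could account for the rise, and the tables do not decide it: the S phase mean rose by 0.46 more than the mitosis mean on the log2 scale, with a one-sided exact permutation p of 0.0571 (two-sided 0.0857; the smallest one-sided p is 0.0286). The rule for this test was rewritten after its value had been seen, because its first form would have read a p above 0.05 as a fit. Another split gave as large a difference, which keeps it open, and whether the mitosis list is called depends on the setting: it was called with all libraries under limma voom (camera adjusted p = 0.00662, 15 members higher against 7), and without control replicate 3 (0.0465) or Adssl1 replicate 3 (0.0332).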

How the results depend on the processing

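Leaving out Adssl1 replicate 4 and control replicate 3 together was the 1 alternative chosen after seeing the data. The number of changed genes stayed within 1.5 times of 7349 under each alternative scaling, filter and tool (6964 with total counts only to 9347 with limma voom; DESeq2 7243) and was 6978 without both farthest libraries. It was 1954 with a 2-fold minimum, which by construction counts fewer genes. Leaving out 1 library gave 5874 to 7022 genes, 2796 to 3455 higher and 3078 to 3571 lower, Adss1 log2 fold changes of 10.83 to 11.33, and 13 to 16 called lists. No gene called in both the main test and an alternative changed sign. Called lists numbered 0 with the correlation estimated per list. Among the lists called in the main test the estimates ran from 0.058 (Cdk inhibitors and p53 targets) to 0.818 (cholesterol and fatty acid synthesis). All of them lay above the preset 0.01. Of 112 named genes, 7 lost their call in some setting.

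The correlations gave no sign that the replicate numbers pair the samples. They were 0.03, 0.05 and 0.03 for same-numbered libraries and -0.11 to 0.12 for the others. They cannot exclude pairing in single gene groups. The interferon list was lowest in replicate 3 of both groups, as was Mx1 (8.72 CPM in the controls, 1.49 CPM with Adssl1). The hypoxia list in replicate 3 was highest in the controls (0.73) and lowest with Adssl1 (-0.49). Whether same-numbered libraries share a source was not tested. With a replicate block 6693 genes changed (3239 higher, 3454 lower), Adss1 stood at 10.85 and 14 lists were called.

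Results that turned direction were all uncalled in the main test. The list of endothelial markers turned under RLE scaling (camera adjusted p = 0.998), without both farthest libraries (0.906) and in some settings with 1 library left out (range of camera adjusted p over them all, 0.624 to 0.934). The smooth muscle and pericyte markers list turned under voom (0.723). With 1 library left out the interferon and antiviral response list (0.0322 to 0.935) and the hypoxia response list (0.0188 to 0.952) each turned in some settings, and each was called in 1 of these settings in its main direction. Mki67 turned under the replicate block (log2 fold change -0.0750) and in some settings with 1 library left out (-0.0831 to 0.186). Mycn turned only without control replicate 2 (0.0258, range with 1 library left out -0.151 to 0.0258). The cause was not tested for either gene. Without both farthest libraries ribosome biogenesis lost its call (0.0506), while the interferon list (0.00508, 14 lower) and mitochondrial transcripts (0.0410) gained one. Voom lost the immediate-early list (0.0538) and gained mitosis (0.00662), mitochondrial transcripts (0.00362) and cytosolic ribosomal proteins (0.0136). With no low-count filter calcium handling (0.0201), glycolysis (0.0359) and mitochondrial transcripts (0.0201) were gained, and with the replicate block mitochondrial transcripts (0.0475, 8 lower).

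Member counts that moved by more than 1.5 times with all libraries kept were as follows. With the replicate block, purine synthesis had 6 higher and 1 lower, mitosis 4 higher, fatty acid oxidation 2 higher, interferon 9 higher and 13 lower, ribosome biogenesis 8 higher, endothelial 7 lower and epicardial 4 lower. With no low-count filter, calcium handling had 1 higher, glycolysis 3 lower, interferon 0 higher and 2 lower, cytokines 4 higher and endothelial 2 lower. With voom, purine synthesis had 5 lower, S phase 1 lower, mitosis 15 higher, cyclin D and Myc 5 lower, calcium handling 4 higher, fatty acid oxidation 2 higher, mitochondrial transcripts 11 lower, fibroblast 1 higher, endothelial 4 lower, smooth muscle 5 higher and epicardial 4 lower. With total counts only, purine synthesis had 1 lower, fatty acid oxidation 1 higher and Hippo-Yap 2 lower. DESeq2 gave 2 lower endothelial and 4 lower epicardial members, thinning 2 lower endothelial members, and the filter on CPM 1 higher Schwann member.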

Other observations

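All lists and tests in this part were chosen after the data had been seen. Targets of the oxidative stress factor Nrf2 rose: 14 of 20 were higher and none lower (median log2 fold change 0.51; camera adjusted p = 8.90e-08 over 4 added lists; adjusted p = 0.0248 with an estimated correlation). Srxn1 rose by 2.02 (SE 0.12), Osgin1 by 1.99 (SE 0.14), and Gclc, which makes a glutathione precursor, by 1.09 (SE 0.07), while Nqo1 did not pass (0.64, SE 0.24; edgeR adjusted p = 0.0576). Heat shock and chaperone genes rose, 12 of 20 higher and none lower (median 0.29; camera adjusted p = 2.06e-06; adjusted p = 0.0209 with an estimated correlation), with Hsph1 at 1.45 (SE 0.15) and Hsp90aa1 at 1.10 (SE 0.11). Of 6 tested ligands of the Erbb receptors 4 were higher and none lower (median 1.32; camera adjusted p = 4.55e-05; adjusted p = 0.0209 with an estimated correlation), led by Areg (3.61, SE 0.18), Ereg (2.25, SE 0.22) and Tgfa (2.22, SE 0.13). Since these genes were picked after many of them had been seen among the rises, the tests are not independent evidence. In the same libraries leukocyte markers had a median of -4.13.

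Of 37 tested collagen chain genes 20 were lower and 6 higher, with a median log2 fold change of -0.46. Fibroblast and matrix markers, some of them collagens, fell with them (median -1.15, 15 of 21 lower).

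Adssl1 replicate 4 held 14.2% Adssl1 counts against 7.47% to 7.84% in the other 3. A hypothesis that the response may grow with the Adssl1 level was tested by the slope of each library's fold changes on the mean of the other 3, over genes called without it. The slope was 0.957 for replicate 4 and 0.974, 0.969 and 0.959 for replicates 1 to 3, so the slopes gave no sign of a larger response in replicate 4. The rule for this test was rewritten after its value had been seen. Its first form would have read this value as excluding the hypothesis. In mean list levels, of the 13 called lists replicate 4 lay farther from the controls than the other 3 libraries for 5, nearer for 4 and between them for 4. The 5 were sarcomere genes (-1.26 against -0.91 to -0.83), oxidative phosphorylation (-0.88 against -0.67 to -0.56), fatty acid oxidation (-0.50 against -0.45 to -0.30), immediate-early genes (0.43 against 0.21 to 0.31) and the purine list that holds Adssl1 itself (0.83 against 0.71 to 0.81). The 4 were fibroblast markers (-0.94 against -1.24 to -1.16), leukocyte markers (-3.42 against -4.03 to -3.63), cholesterol synthesis (-0.59 against -0.87 to -0.75) and integrated stress (-0.23 against -0.53 to -0.38). Of the 15 lists that were not called, counted along the mean of the Adssl1 libraries, 3 lay beyond (cytokines, 1.30 against 0.04 to 0.27, mitosis and epicardial markers), 7 short of and 5 between the other 3. The tables therefore leave open whether the response grows with the Adssl1 level.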
